A study of Mus musculus with 4 samples.

How the data were processed

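The series holds 4 single-cell RNA libraries of mouse small-intestinal crypt cells, 2 from syngeneic and 2 from allogeneic marrow recipients 7 days after transplantation. Per the labels' protocols, each library pools 3 to 4 female mice aged 8 to 12 weeks; crypts were released in 10 mM EDTA for 40 minutes at 4 °C, passed through a 70 µm strainer, digested with TrypLE for 20 minutes at 37 °C and passed through a 40 µm strainer. Libraries were made with the 10x Genomics Chromium Single Cell 3′ kit and sequenced on a NovaSeq, per the labels. The values used are UMI counts per gene and cell, as deposited by the authors; they are not normalised. Per the submitters' processing notes the counts were made with Cell Ranger 2.1.1 on mm10, while the header of the deposited matrices gives software version 3.1.0. The annotation release and the rule by which barcodes were kept are not given in the sources used here; no deposited barcode holds fewer than 500 UMIs. Dense text copies of the same counts were deposited and not used here. The labels give no cell annotation and no batch. Replicate numbers follow the order of the sample records and pair no libraries.

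Per library, in the order syngeneic 1, syngeneic 2, allogeneic 1 and allogeneic 2, the total counts were 18262459, 14961466, 16755124 and 26677842 UMIs. Cells with at least 500 genes and 1000 UMIs and at most 20% mitochondrial counts were kept, which passed 12285 of 16565 barcodes. Scrublet, as in scanpy, called 108 of these doublets (0.88%), which were removed. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 23 clusters. The response lists were left out of the variable genes, so that the response itself would not define clusters. A cluster took the name of the class whose fixed markers scored highest (a mean z-score of at least 0.5 with at least 3 markers detected), unless its 10 leading genes held more markers of another class, or it had few UMIs and no such marker; otherwise it stayed unnamed; unnamed cells (166, 154, 82 and 473 per library) count as epithelial cells without a class. Gene positions are those of GENCODE M21 (GRCm38/mm10).

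Counts were summed per class and library, and a class was tested where each library held at least 20 cells. T or NK-like cells missed this limit, with 10 cells in syngeneic 1. Genes were filtered with filterByExpr, scaled with TMM and tested with edgeR's robust quasi-likelihood fit, allogeneic against syngeneic, with Benjamini-Hochberg adjustment over the genes of the class and a threshold of 0.05. Class shares were tested with an edgeR quasi-likelihood fit on cells per class over 9 classes, without TMM, the robust option or a trend with abundance. The size of a library was its epithelial cells, or all kept cells for T or NK-like and myeloid-like cells. The spread was estimated over all 9 classes together. The difference of the allogeneic effect between classes was tested as an interaction with library as a block. There were 25 fixed gene lists and 13 marker lists, tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, and with fry. A list's counts are given over all genes tested and adjusted over the list alone. Detection shares were computed after thinning each cell to 2000 UMIs, which left out 197, 243, 181 and 640 epithelial cells with fewer. Intervals are exact 95% binomial (Clopper-Pearson) or Poisson intervals and cover counting error only, and a count of 0 is bounded by 3 counts.

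With 2 pools per group, the comparison rests on 2 against 2. Data were simulated at the same depth, with the fitted spread of each gene used for both groups. There, edgeR recovered 96.8% of genes changed 4-fold and 44% of those changed 2-fold in stem-like cells, 81.6% and 8.2% in all epithelial cells, 97.9% and 44.4% in cycling progenitor-like, 80.8% and 21.6% in enterocyte-like and 94.7% and 34.3% in Paneth-like cells, but 0 in goblet-like cells at either fold, where DESeq2 recovered 38.3% and 4.1%. In the real epithelial sums the SD of the log2 difference within the allogeneic pair was 3.114 times that within the syngeneic pair. The simulated rates do not cover such unequal spread. Beside the recovered genes of both folds, edgeR made false calls: 5 beside 91 and 44 in stem-like, 8 beside 80 and 8 in epithelial, 16 beside 94 and 44 in cycling progenitor-like, 14 beside 80 and 21 in enterocyte-like, 13 beside 89 and 34 in Paneth-like, 16 beside 77 and 23 in enteroendocrine-like and 12 beside 73 and 11 in tuft-like cells. In 6 of these 7 fits the false share exceeds the threshold of 0.05. Camera with the preset correlation found a simulated changed list in each of the 8 fits and called none of 20 unchanged lists, while with an estimated correlation it missed the changed list in each, with adjusted p values of 0.154 to 0.379. The simulated genes varied independently of each other. This check therefore cannot tell whether the preset correlation calls too many lists of genes that vary together.

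The lists, the classes, the main settings and most alternatives were chosen before the data were examined. Genes were named by a rule chosen then: in epithelial and stem-like cells, among called genes with both allogeneic libraries on the same side of both syngeneic ones and a mean of at least 20 CPM, the 8 largest rises and the 8 largest falls (3 each way in other classes), a fixed panel of crypt, interferon and stress genes, and up to 4 members per list with the smallest adjusted p. Predicted genes, unnamed clones, mitochondrial and ribosomal protein genes were left out of the first part. Which of the genes under the rule serve as examples was chosen after their values were seen. Genes named as leading a cluster, or at 0 in a group, or in lymphocytes, stand outside the rule and were chosen after their values were seen. Alternatives covered the normalization, the gene filter, the cell filters, doublets, the clustering, the test and each library left out. Removing the cells with the highest doublet scores (0.8% per 1000 cells), leaving out unnamed clusters and clustering without called genes were added later. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.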

Results

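Cells of small-intestinal crypts were profiled by droplet-based single-cell RNA sequencing 7 days after lethal irradiation and bone marrow transplantation. Recipients were C57BL/6 mice that received marrow of their own strain (syngeneic, labelled control) or of BALB/c donors (allogeneic). The names of all 4 libraries begin with "KO", which the labels do not explain. An allogeneic graft can attack the tissues of its host, which is graft-versus-host disease, and the series title names intestinal stem cells in mice with that disease. The comparison therefore asks how crypt cells, and stem cells among them, differ between the 2 kinds of transplant. Each group had 2 libraries, each made from a pool of 3 to 4 mice, so that n = 2 pools per group for every value below. Values per library are given in the order syngeneic 1, syngeneic 2, allogeneic 1 and allogeneic 2, called library order here.

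In library order, the deposited barcodes numbered 3580, 3257, 3387 and 6341, with total counts of 18262459, 14961466, 16755124 and 26677842 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule). After filtering, 12177 cells were kept, namely 2870, 2457, 2053 and 4797 in library order. Their median depths were 4521, 4201, 5182 and 3939 UMIs per cell. The share of barcodes above the limit on mitochondrial counts, a sign of damaged cells, was 27.2% in allogeneic 1, against 14.6%, 14.9% and 11.2% in the other libraries.

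The kept cells formed 23 clusters, which were named from fixed marker genes and are called stem-like, cycling progenitor-like and so on, since the labels give no cell annotation. In library order the stem-like class held 414, 233, 346 and 55 cells, and the cycling progenitor-like class held 640, 495, 476 and 1630. Enterocyte-like cells, the absorptive class, numbered 632, 662, 370 and 1975. Paneth-like cells, which make antimicrobial peptides, numbered 330, 303, 204 and 145, and mucus-making goblet-like cells numbered 561, 503, 270 and 252. The hormone-making enteroendocrine-like class held 57, 38, 28 and 28 cells, and the chemosensory tuft-like class held 60, 37, 33 and 40. T or NK-like lymphocytes numbered 10, 32, 231 and 194.

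The 2 allogeneic libraries stood apart from each other. Over genes, the SD of the log2 difference between the 2 libraries of a group was 0.223 for the syngeneic pair and 0.667 for the allogeneic pair, against 0.498 to 0.717 for pairs across groups. Different clusters held some classes in the 2 groups. Cycling progenitor-like cells came mostly from clusters 2 and 14 in the syngeneic libraries (428 and 305, and 192 and 169 cells). In the allogeneic libraries most came from clusters 1 (145 and 932 cells) and 5 (126 and 658 cells). Leading genes of cluster 5 included the interferon-response genes Cxcl9, Cxcl10, Ido1, Iigp1 and Gbp2 and the antimicrobial gene Retnlb. Among stem-like cells, cluster 16 held 269 of the 346 cells of allogeneic 1 and was led by Slpi, Olfm4, H2-Q6 and the early-response gene Egr1. Cluster 6 held most of the others, with 394, 220, 77 and 35 cells in library order. Enterocyte-like cells of allogeneic 2 lay mainly in clusters 0 (1090 cells) and 3 (874 cells), and those of allogeneic 1 in cluster 17 (278 cells, median mitochondrial share of the cluster 15.05%).

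T or NK-like lymphocytes made up a larger share of the cells in both allogeneic libraries. Because the genes that changed could themselves pull cells into other clusters, shares were read first from a second clustering that left out 918 genes called in any class. There, T or NK-like cells were 0.383%, 1.302%, 11.203% and 4.128% of kept cells in library order, a log2 ratio of 3.18 (higher in 2 of 2 allogeneic libraries) that did not pass the test (edgeR, adjusted p = 0.262 over 9 classes). In the first clustering the shares were 0.348%, 1.302%, 11.252% and 4.044%, with exact 95% binomial intervals of 0.167 to 0.64, 0.893 to 1.834, 9.917 to 12.699 and 3.504 to 4.641. The group means were 0.825% ± 0.675 and 7.648% ± 5.097 (SD, n = 2 pools), a log2 ratio of 3.21 with an adjusted p of 0.0471. Over all alternatives the adjusted p ran from 0.000435 to 0.846. It was 0.846 without syngeneic 1 (log2 ratio 2.55) and 0.273 without syngeneic 2 (4.44), and without allogeneic 1 or 2 it was 0.0077 and 0.000435. Myeloid-like cells numbered 18, all allogeneic (13 and 5), and 0 of the 5327 syngeneic cells were myeloid-like, which allows a share of up to 0.0563%. The adjusted p of that class was 0.0467 in the first clustering and 0.262 without the called genes; with classes assigned per cell its log2 ratio was -0.25 (0.738).

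Among epithelial cells, none of the 7 classes passed the test of its share. In the clustering without called genes, stem-like cells made up 18.748%, 12.289%, 22.044% and 5.529% of epithelial cells in library order. Goblet-like cells made up 9.094%, 10.062%, 5.691% and 3.352%, and Paneth-like cells 10.913%, 12.0%, 9.558% and 3.526%. That clustering had 3 goblet and 4 Paneth markers left for naming, and a cluster led by the goblet genes Agr2, Tff3, Spdef and Muc2 stayed unnamed in it (282, 242, 209 and 484 cells), so the goblet-like shares leave these cells out. Enterocyte-like cells made up 22.001%, 27.546%, 21.326% and 45.755%. In that clustering the log2 ratio was -0.18 for stem-like (adjusted p = 0.845), -0.81 for Paneth-like (0.534) and -1.09 for goblet-like cells (0.262). In the first clustering each had an adjusted p of 0.809, over ranges of 0.00282 to 0.962 for stem-like, 0.0131 to 0.962 for Paneth-like and 0.0131 to 0.962 for goblet-like cells across alternatives. The low ends are from leaving out allogeneic 1, when the ratios were -3.33, -1.93 and -1.88 against a single allogeneic library. A test of 2 against 2 libraries by exact permutation could not go below 0.333 (two-sided).

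**Figure D1:**
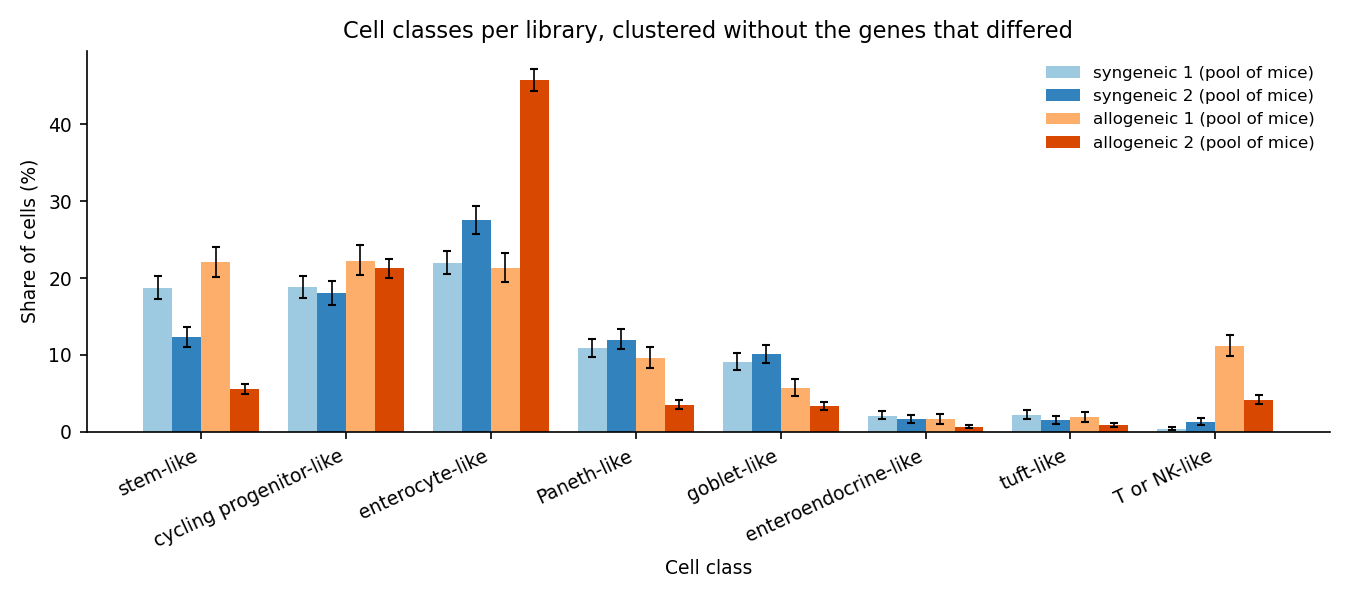
Share of cells per class (%, linear axis from 0) in each of the 4 libraries, clustered without the called genes; bars are libraries and error bars are exact 95% binomial intervals, with T or NK-like cells as a share of all kept cells and the other classes as a share of epithelial cells. Stem-like cells range from 5.529% in allogeneic 2 to 22.044% in allogeneic 1, and T or NK-like cells reach 11.203% in allogeneic 1.

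Across all epithelial cells, interferon-response genes were higher after allogeneic transplantation. Cxcl9 (ENSMUSG00000029417, GRCm38/mm10 chromosome 5, 92321347 to 92328079), a chemokine that attracts activated T cells, averaged 226 ± 146 CPM (UMI counts scaled to the depth of the library) in the allogeneic and 2.06 ± 0.279 in the syngeneic libraries (SD, n = 2 pools). Its log2 fold change was 6.78 (SE 0.63, edgeR adjusted p = 0.0343). Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008), an interferon-induced GTPase, averaged 136 ± 39.6 against 7.95 ± 0.93 CPM, and Iigp1 (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634), from another family of such GTPases, 229 ± 41.1 against 21.8 ± 3.16. Reg3a (ENSMUSG00000079516, chromosome 6, 78380709 to 78383827), a secreted antibacterial lectin, fell from 51.0 ± 7.49 to 5.84 ± 0.0733 CPM, a log2 fold change of -3.12 (SE 0.22, adjusted p = 0.0233). The other gene that fell was Cyp2d26, a cytochrome P450 gene (-3.11, adjusted p = 0.0478).

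Of the 12038 genes tested in epithelial cells, 17 rose and 2 fell, and in all 19 both allogeneic libraries lay on the same side of both syngeneic libraries. Over all tested genes 41.1% were split in this way, against 33.3% by chance. Of 26 measured interferon-gamma-inducible GTPases and regulators, 8 rose over all genes (25 when adjusted over the list alone), with a median log2 fold change of 2.78. Gbp5 (5.39), Gbp3 (3.60) and Gbp7 (2.38) were among them, although near-identical Gbp genes can share reads. Of 18 genes of MHC class I presentation and the immunoproteasome, which present peptides to CD8 T cells, 1 rose over all genes and 15 when adjusted over the list alone (median 1.24). Among them B2m, the shared light chain, had a log2 fold change of 1.92 that did not pass (edgeR adjusted p = 0.166). Its fold change was 2.196 without allogeneic 1 and 1.539 without allogeneic 2, in fits whose spread comes from the syngeneic pair alone. Of 9 genes of MHC class II presentation, H2-DMb2 rose (5.88) over all genes and 8 rose when adjusted over the list alone (median 1.001). The interferon-stimulated genes shared with type I interferon had a median of 1.45, with 1 of 24 members called over all genes and 15 when adjusted over the list alone. Competitive set tests (camera, preset correlation) called these 4 lists higher, with adjusted p values of 5.11e-75, 3.14e-24, 2.68e-15 and 1.52e-27 in the order given here, and each had an adjusted p of 0.203 with an estimated correlation.

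Genes linked to regeneration of damaged epithelium were higher as a list (19 members, median 0.88, camera adjusted p = 3.18e-08, and 0.283 with an estimated correlation), with 0 called over all genes by edgeR and 3 adjusted over the list alone. Its member Ly6a, which codes for Sca-1, had a log2 fold change of 5.18 that did not pass (adjusted p = 0.11; 39.0 ± 9.55 against 1414 ± 1175 CPM). Leaving out 1 library gave Ly6a log2 fold changes of 4.926, 5.453, 5.834 and 3.903 in library order. In each of these fits 1 group held a single library, whose spread was taken from the other group. Early-response and heat-shock genes, which enzymatic dissociation can also raise, had a median of 0.49 (1.2e-05, and 0.203 with an estimated correlation). That list was also called higher in each of the 7 classes. Its medians were 0.64 in enterocyte-like (camera 0.0153, and 0.521 with an estimated correlation), 0.69 in goblet-like (0.00164, and 0.664), 0.85 in enteroendocrine-like (1.53e-08, and 0.758) and 0.65 in tuft-like cells (0.0031, and 0.425). The call was lost in enterocyte-like cells without syngeneic 1 or allogeneic 2 (0.0549 and 0.198; range 0.00201 to 0.521), in goblet-like cells without allogeneic 2 (0.176; range 4.62e-06 to 0.711) and in tuft-like cells without allogeneic 1 (0.121; range 0.000206 to 0.425). Cell death machinery genes were called higher in epithelial cells (median 0.25, camera 0.0494, and 0.691 with an estimated correlation), Paneth-like cells (0.31, 0.00519, and 0.325) and goblet-like cells (0.51, 0.011, and 0.664). By edgeR 0 of 26, 1 of 21 and 0 of 26 members rose (0, 2 and 0 adjusted over the list alone). These calls were lost without syngeneic 1, syngeneic 2 or allogeneic 2 in epithelial cells (0.114, 0.315 and 0.482; range 0.00171 to 0.691), without syngeneic 1, allogeneic 1 or allogeneic 2 in Paneth-like cells (0.107, 0.166 and 0.0993; range 0.005 to 0.325) and without syngeneic 2 or allogeneic 2 in goblet-like cells (0.2003 and 0.991; range 0.00133 to 0.991). Xenobiotic and retinoid metabolism genes were lower as a list (22 members, median -0.89, 2.42e-10, and 0.203 with an estimated correlation), with 1 member down over all genes and 10 down and 1 up when adjusted over the list alone. Genes of the proximal small intestine were lower beside them (14 members, median -0.38, mean -1.05, camera 2.62e-05, and 0.203 with an estimated correlation), with 0 called over all genes by edgeR and 5 down and 1 up adjusted over the list alone. That call was lost without allogeneic 1 (0.257; range 2.065e-05 to 0.257). Markers of Paneth cells (median -1.94, 3e-15, and 0.33 with an estimated correlation), goblet cells (-1.01, 2.29e-07, and 0.206) and enteroendocrine cells (-0.86, 2.59e-05, and 0.229) were lower as lists. In the first clustering Paneth-like cells were 11.538%, 12.495%, 11.277% and 3.154% and goblet-like cells 19.615%, 20.742%, 14.925% and 5.481% of epithelial cells in library order. Stem-cell markers had a median of -0.33 (0.0137, and 0.756 with an estimated correlation), which was 0.11 without allogeneic 2 (camera 0.482; range 2.92e-07 to 0.756). Markers of T and NK cells were not called in epithelial cells (median -0.18).

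The count of changed epithelial genes depended on single libraries: in library order, leaving each out gave 96, 110, 5719 and 2975 genes, each set including the 19. It was 0 (edgeR) with a mitochondrial limit of 10% (1009 genes at an unadjusted p under 0.05) or with a minimum of 20 CPM (395 unadjusted). DESeq2 called 331 (195 higher and 136 lower), and edgeR with an equal mix of classes 203 (124 higher and 79 lower). The main fit's lean toward rises was thus weaker in these 2 settings.

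**Figure D2:**
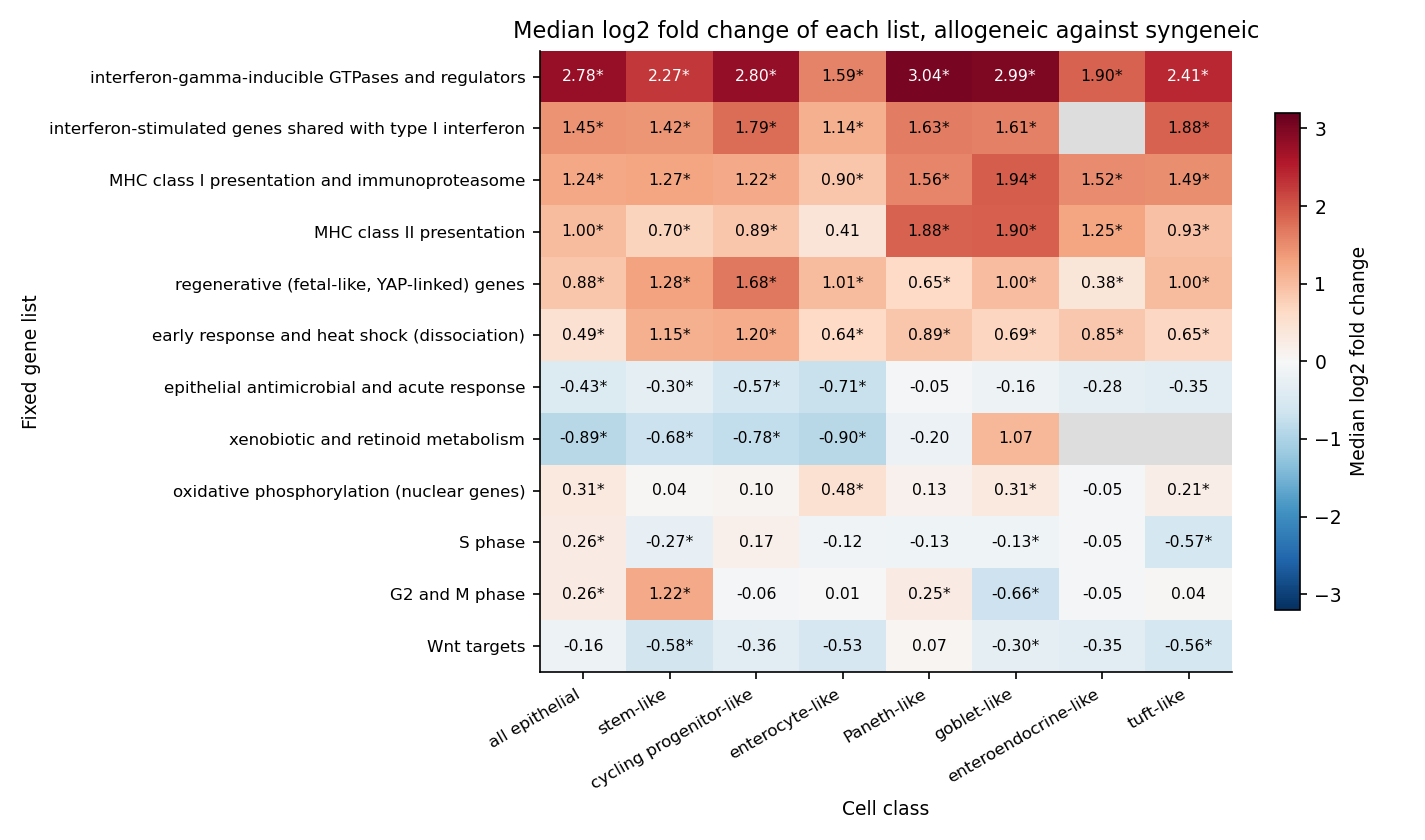
Median log2 fold change (colour and number, allogeneic against syngeneic) of 12 fixed gene lists in all epithelial cells and in 7 classes; an asterisk stands for a camera adjusted p under 0.05 with the preset correlation, and grey for too few measured members. The interferon-gamma list is positive in each class, from 1.59 in enterocyte-like to 3.04 in Paneth-like cells.

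Ly6a was found in more epithelial cells of both allogeneic libraries when each cell was thinned to 2000 UMIs. It was detected in 5.407%, 6.783%, 46.437% and 79.005% of cells in library order, means of 6.10% ± 0.973 and 62.7% ± 23.03 (SD, n = 2 pools). Olfm4, a stem-cell marker, was detected in 38.1% ± 5.83 of syngeneic and 28.8% ± 17.7 of allogeneic epithelial cells. Lgr5, the classical marker of crypt base stem cells, was detected in 5.06% ± 0.486 and 4.10% ± 3.33, and the proliferation marker Mki67 in 14.6% ± 1.45 and 15.46% ± 8.19. For these 3 genes the difference of the means was smaller than the allogeneic SD. As background for free RNA, T or NK-like cells of allogeneic 1 and 2 had a UMI of Olfm4 in 3.49% of 86 and 0 of 70 cells (which allows up to 4.29%), and of Lgr5 in 0 of 86 (up to 3.49%) and 0 of 70. For Ly6a, which T cells can also express, these shares were 4.65% and 22.9%. Median depths before thinning were 6214 and 4604 UMIs in epithelial and 2873 and 2592 in T or NK-like cells of the same libraries. Clu, a marker of revival stem cells, was detected in 0.548% ± 0.127 and 0.426% ± 0.353 of epithelial cells. The T or NK-like cells had it in 1.16% of 86 (exact 95% interval 0.029 to 6.309) and 0 of 70 cells (up to 4.29%), too few to compare it with background.

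**Figure D3:**
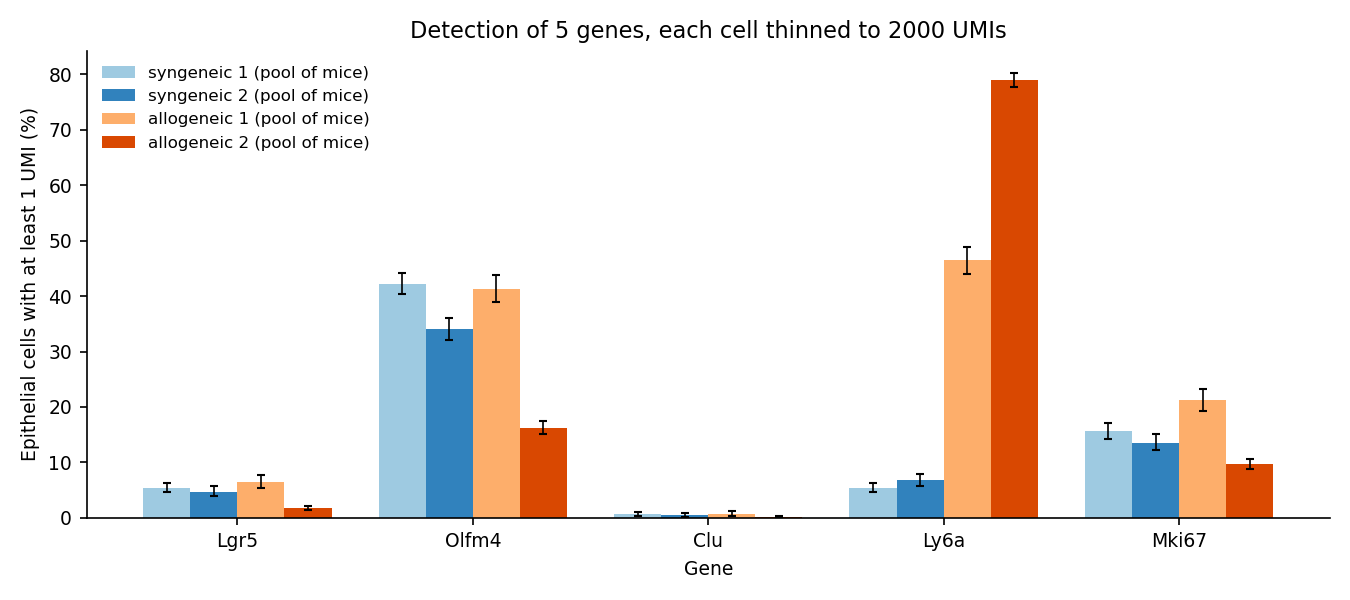
Epithelial cells with at least 1 UMI of each of 5 genes (%, linear axis from 0) after thinning each cell to 2000 UMIs; bars are the 4 libraries and error bars are exact 95% binomial intervals. Ly6a is at 5.407% and 6.783% in the syngeneic and at 46.437% and 79.005% in the allogeneic libraries.

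Stem-like cells of the allogeneic group had higher interferon-response and antigen-presentation genes and lower Olfm4, and lower counts of the antimicrobial Reg3 genes. Ubd (ENSMUSG00000035186, chromosome 17, 37193892 to 37196095), a ubiquitin-like modifier induced by interferon gamma, rose from 2.13 ± 2.00 to 226 ± 92.1 CPM (SD, n = 2 pools), a log2 fold change of 6.75 (SE 0.50, adjusted p = 2.17e-07). Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031) rose from 29.8 ± 4.59 to 1003 ± 719 CPM (5.04, SE 0.48, adjusted p = 2.48e-05). Ido1 (ENSMUSG00000031551, chromosome 8, 24584136 to 24597009), which breaks down tryptophan, had 2 counts in the syngeneic and 482 in the allogeneic libraries, a ratio of 197.6 per UMI with a 95% counting interval of 54.4 to 1637. Reg3g (ENSMUSG00000030017, chromosome 6, 78466269 to 78468872) fell from 3929 ± 120.0 to 959.6 ± 30.1 CPM (-2.03, SE 0.23, adjusted p = 2.6e-05), and Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466) from 7005 ± 815 to 2138 ± 293 (-1.71, adjusted p = 0.000129). In T or NK-like cells, taken as a gauge of free RNA, Reg3g stood at 353.5, 6425, 464.9 and 1636 CPM in library order. Reg3b stood at 176.8, 15260.0, 1455 and 5961 CPM. The Reg3 counts of stem-like cells are thus not shown to exceed free RNA in syngeneic 2 or allogeneic 2. In syngeneic 1, with 10 T or NK-like cells, and in allogeneic 1 these levels lay below the stem-like group means. The gauge is rough: Defa21 stood at 2062 CPM in syngeneic 1 and at 0 in syngeneic 2, with 32 such cells. Doublets of lymphocytes with epithelial cells were not told apart from free RNA in it.

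Of 8216 genes tested in stem-like cells, 162 rose and 62 fell, and 216 of the 224 separated the groups library by library. The share over all genes was 39.5%, against 33.3% by chance. Of 22 interferon-gamma-inducible GTPases and regulators, 17 rose (22 adjusted over the list alone), among them Gbp2 (3.86, 11.9 ± 1.57 to 179.5 ± 32.4 CPM). Of 14 interferon-stimulated genes shared with type I interferon, 7 rose (11 adjusted over the list alone), for example Bst2 (1.94). MHC class I and immunoproteasome genes had 11 of 17 members up (12 adjusted over the list alone), including H2-Q7 (2.46) and B2m (1.53). H2-Q6, which is not on that list, rose by 3.94 on the log2 scale. H2-Q genes are near-identical copies, so their counts could be split among them in error. MHC class II genes had 3 of 9 members up (7 adjusted over the list alone). The medians of these 4 lists were 2.27, 1.42, 1.27 and 0.70, each called by camera. With an estimated correlation their adjusted p values were 0.108, 0.243, 0.108 and 0.148. Of the 12 regeneration-linked genes 4 rose (6 adjusted over the list alone), including the calcium-binding S100a6 (1.76), with a list median of 1.28 (camera 1.37e-08, and 0.148 with an estimated correlation).

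Of the stem-cell genes, Olfm4 and Ascl2 fell in stem-like cells, while Lgr5 and Smoc2 did not pass. Olfm4 (ENSMUSG00000022026, chromosome 14, 79984081 to 80023139) fell from 6056 ± 104 to 2681 ± 82.9 CPM (-1.17, SE 0.21, adjusted p = 0.0029). Without syngeneic 1 or syngeneic 2 its adjusted p was 0.587 and 0.407, and over all alternatives 4.06e-25 to 0.587. Ascl2, a transcription factor of crypt base stem cells, fell by 1.26 on the log2 scale (adjusted p = 0.0329), and its adjusted p was 1.0, 0.0635 and 0.228 without syngeneic 1, syngeneic 2 or allogeneic 1 (all alternatives 8.05e-07 to 1.0). Lgr5 had 112 ± 6.27 against 74.8 ± 0.995 CPM (-0.58, edgeR adjusted p = 0.287), and also -0.58 without allogeneic 2. Smoc2 had a log2 fold change of -0.44 (edgeR adjusted p = 0.515). These 4 genes were also among the markers that defined the class. Markers of other classes moved in the same cells: 7 of 14 cycling progenitor markers rose (8 adjusted over the list alone; median 0.84, camera 4.05e-07, and 0.244 with an estimated correlation). Of 8 goblet markers 2 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.75, camera 0.00402, and 0.243 with an estimated correlation). Of 14 stem-cell markers 3 fell (4 adjusted over the list alone; median -0.54, camera 2.03e-07, and 0.243 with an estimated correlation). Wnt targets, which stem cells maintain, had 1 of 13 members down (6 adjusted over the list alone; median -0.58, camera 0.000242, and 0.243 with an estimated correlation). Gkn3 had 0 counts in the allogeneic libraries and was at least 11.2-fold lower, from a floor of 3 counts over the group. That bound rests mainly on allogeneic 1, with 2569755 UMIs in stem-like cells against 213598 in allogeneic 2. Ccl25, a chemokine that draws T cells to the small intestine, fell by 1.99 on the log2 scale (198.8 ± 29.3 to 44.5 ± 14.1 CPM), but T or NK-like cells held 412.4, 83.0, 51.03 and 38.84 CPM of it in library order, so it too is not shown to exceed free RNA. The value of syngeneic 1 is 7 UMIs in 10 cells.

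Genes of the G2 and M phases were higher in the stem-like class, with 18 of 25 members up (25 adjusted over the list alone), among them the mitotic genes Ube2c (1.66) and Cenpa (1.45). The list median was 1.22 (camera 1.29e-27, and 0.243 with an estimated correlation). S-phase genes had a median of -0.27 (0.0131, and 0.747 with an estimated correlation), a call lost without syngeneic 2 (0.423) or allogeneic 1 (0.809; range 0.000521 to 0.809). Mki67 rose by 1.16 (adjusted p = 0.0368), but did not pass without syngeneic 1, syngeneic 2 or allogeneic 1 (1.0, 0.2605 and 0.666; all alternatives 9.22e-13 to 1.0), and its log2 fold change was -0.43 with a mitochondrial limit of 40% and -0.090 with classes assigned per cell. Early-response and heat-shock genes rose in 10 of 21 members (14 adjusted over the list alone), with a median of 1.15 (1.3e-19, and 0.148 with an estimated correlation); Egr1 rose by 2.66, Klf6 by 2.11 and the chaperone gene Hspa1a by 4.03. The median mitochondrial share of stem-like cells was 7.73%, 7.71%, 9.42% and 5.74% in library order, and their total depth in allogeneic 2 was 213598 UMIs against 860347 to 2569755 in the other libraries.

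Leaving out each library in turn gave 40, 64, 331 and 1180 changed genes in stem-like cells, in library order, of which 36, 54, 79 and 224 were among the 224. Of the 34 changed genes named under the fixed rule, 17, 19, 27 and 34 still passed. Without syngeneic 1 or syngeneic 2, the adjusted p was 0.368 and 0.251 for B2m, 0.339 and 0.1765 for Ube2c, 0.4799 and 0.2215 for Cenpa and 0.107 and 0.177 for S100a6, and without syngeneic 1 it was 0.0771 for Reg3b. Over all alternatives it ran from 2.81e-32 to 0.368, 3.21e-23 to 0.991, 2.96e-15 to 0.6615, 1.01e-23 to 0.177 and 4.12e-46 to 0.0771 for these genes in turn. DESeq2 called 54 genes.

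**Figure D4:**
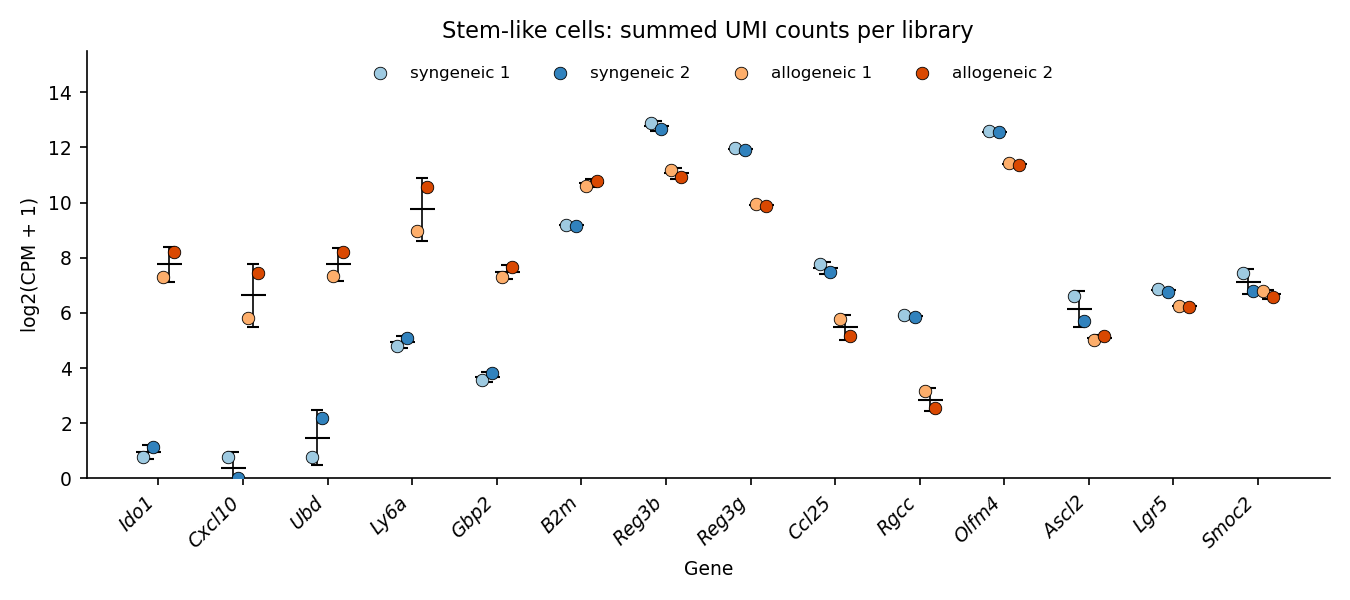
Log2(CPM + 1) of 14 genes in stem-like cells; points are the 4 libraries and lines are group means ± SD (n = 2 pools). Ubd averaged 226 CPM in the allogeneic and 2.13 in the syngeneic group, and Olfm4 2681 and 6056.

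Cycling progenitor-like cells had higher interferon-response genes and, except with a mitochondrial limit of 10%, higher goblet genes. The goblet genes Tff3 (97.4 ± 33.5 to 789.8 ± 176 CPM, SD, n = 2 pools; log2 fold change 3.02) and Muc2 (27.2 ± 9.496 to 219 ± 117 CPM, 3.02) rose, but had log2 fold changes of 1.01 and 0.0097 with that limit (adjusted p = 0.216 and 0.996). Also higher were Spdef (3.83) and Atoh1 (3.13), transcription factors of the goblet and of all secretory lineages, of which Atoh1 did not pass with that limit either (0.68, adjusted p = 0.712). Mmp7, the protease that activates Paneth cell defensins, rose from 27.5 ± 5.50 to 825 ± 263 CPM (4.90, SE 0.36, adjusted p = 1.61e-05), while of 11 Paneth markers 2 rose and 3 fell (4 and 4 adjusted over the list alone) and the list was not called (camera 0.288, and 0.757 with an estimated correlation). Ubd (7.96), Cxcl9 (8.26) and Ly6a (5.58, 38.6 ± 6.18 to 1838 ± 1193 CPM) rose as well. Ccl25 fell by 2.33 (217 ± 25.6 to 43.2 ± 6.21 CPM) and Olfm4 by 1.59 on the log2 scale (2109 ± 347 to 700.1 ± 272 CPM, edgeR adjusted p = 0.0132). Ccl25 stood at up to 412.4 CPM in T or NK-like cells, so it is not shown to exceed free RNA. That highest value is 7 UMIs in 10 cells of syngeneic 1, and syngeneic 2 stood at 83.0 CPM. T or NK-like cells held 1002, 249, 113.4 and 5.179 CPM of Olfm4 in library order. The syngeneic counts lay in 2 of 10 and 1 of 32 cells, so they are not shown to be free RNA.

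Of 10307 genes tested in this class, 377 rose and 270 fell. Of 12 goblet markers 8 rose (11 adjusted over the list alone; median 3.52, camera 1.86e-23, and 0.344 with an estimated correlation). Of 24 interferon-gamma-inducible genes 20 rose (24 adjusted over the list alone; median 2.80), of 18 interferon-stimulated genes 12 rose (14; median 1.79), of 18 MHC class I genes 10 rose (15; median 1.22) and of 9 MHC class II genes 4 rose (9; median 0.89), the second count in each being adjusted over the list alone. Of 17 regeneration-linked genes 9 rose (15 adjusted over the list alone; median 1.68), for example Anxa3 (3.21) and S100a6 (3.58). These 5 lists were each called by camera, with an adjusted p of 0.318 with an estimated correlation. Early-response and heat-shock genes, which dissociation can raise, moved with them: 7 of 21 rose (13 adjusted over the list alone; median 1.199, camera 2.87e-13, and 0.382 with an estimated correlation). Of 13 stem-cell markers 2 fell (3 adjusted over the list alone; median -0.36, camera 0.00136, and 0.523 with an estimated correlation). Among 13 antimicrobial genes 4 fell (6 down and 1 up adjusted over the list alone), including Reg3b (-1.73) and Reg3g (-1.86), of which T or NK-like cells held up to 15260.0 and 6425 CPM; the list median was -0.57 while the mean was 0.27, and camera called it lower (0.000179, and 0.318 with an estimated correlation). That call was lost without syngeneic 2 (0.0837), allogeneic 1 (0.224) or allogeneic 2 (0.202), over a range of 0.000201 to 0.318. Notch1 (-1.28) and Nrarp (-1.27), a receptor and a target of the Notch pathway, fell, and the list of Notch and secretory fate genes was not called (2 of 11 up and 2 down, 3 and 2 adjusted over the list alone; camera 0.291, and 0.637 with an estimated correlation). Gsdmd, the pore-forming effector of pyroptosis, rose by 2.24 and Mlkl, that of necroptosis, by 1.14. Their list, the cell death machinery, had 3 of 26 members up and 1 down (the same adjusted over the list alone) and was not called (median 0.18, camera 0.113, and 0.465 with an estimated correlation).

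In library order, leaving 1 library out gave 284, 369, 3800 and 2044 changed genes in this class, of which 252, 316, 641 and 619 were among the 647. Of 22 named changed genes 16, 18, 22 and 21 still passed. Without syngeneic 1 or syngeneic 2 the adjusted p was 0.34 and 0.1035 for Olfm4 (all alternatives 6.04e-73 to 0.34), 0.1175 and 0.302 for Reg3b (2.04e-78 to 0.302), 0.0606 and 0.186 for Reg3g (4.2e-77 to 0.186) and 0.372 and 0.0708 for Mlkl (2.45e-09 to 0.372). Without syngeneic 1 it was 0.319 for Notch1 (7.92e-12 to 0.484) and 0.0827 for Nrarp (4.37e-11 to 0.0827). With a mitochondrial limit of 10% the log2 fold change of Lyz1 was -0.068 (2.94 with the limit of 20%).

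In enterocyte-like cells Usp18, Bst2, Angptl4 and Herpud1 rose, and Tm4sf4, Reg3a and Slc5a4b fell, in a class that different clusters supplied in the 2 groups. In library order, cluster 7 held 322, 363, 3 and 1 of its cells and cluster 9 held 299, 290, 5 and 2. Cluster 9 was led by Fabp6, Reg3a and Reg3b. Most allogeneic cells lay in clusters 0, 3 and 17. The values below were not taken within single clusters, so a change within a cell and another mix of enterocyte-like cells cannot be told apart. Angptl4, an inhibitor of lipoprotein lipase, rose from 13.1 ± 2.23 to 166 ± 44.7 CPM (SD, n = 2 pools; log2 fold change 3.66, SE 0.33, adjusted p = 0.00499), and Herpud1, part of the degradation of misfolded proteins at the endoplasmic reticulum, from 25.2 ± 5.22 to 224.0 ± 32.5 (3.14, adjusted p = 0.00499). Tm4sf4, a membrane protein of the tetraspanin-like family, fell from 108 ± 6.62 to 8.59 ± 4.99 CPM (-3.84, adjusted p = 0.00778), and Reg3a from 173 ± 8.24 to 15.9 ± 9.08 (-3.56, adjusted p = 0.00837). Slc5a4b fell by 3.67 on the log2 scale. Slc5a1, the main glucose transporter of the brush border, rose by 1.75 (509 ± 29.7 to 1713 ± 169 CPM, adjusted p = 0.0363), which did not pass without syngeneic 1 or 2 (0.646 and 0.627; all alternatives 5.23e-14 to 0.646).

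Of 8216 genes tested in enterocyte-like cells, 110 rose and 73 fell. Interferon-stimulated genes shared with type I interferon had 8 of 20 members up (11 adjusted over the list alone; median 1.14), including Usp18 (3.48) and Bst2 (2.91). The interferon-gamma list had 6 of 20 members up (13 adjusted over the list alone), and MHC class I genes 2 of 18 (9 adjusted over the list alone; median 0.90). These 3 lists were called by camera, and their adjusted p values with an estimated correlation were 0.437, 0.521 and 0.437. MHC class II genes were not called (median 0.41, camera 0.154, and 0.521 with an estimated correlation), with 0 of 8 members called by edgeR (0 adjusted over the list alone). Genes of the unfolded protein response had a median of 0.52 (2 of 20 up, 5 adjusted over the list alone; camera 0.000114, and 0.437 with an estimated correlation). Among regeneration-linked genes, 3 of 12 rose (4 adjusted over the list alone), including the growth factor gene Areg (2.84), with a median of 1.01 (camera 1.23e-06, and 0.437 with an estimated correlation). Xenobiotic and retinoid metabolism genes had 3 of 21 members down (2 up and 7 down adjusted over the list alone; median -0.90, camera 0.000299, and 0.521 with an estimated correlation), among them Cyp2c68 (-3.71) and the retinol dehydrogenase gene Rdh7 (-1.75). Without allogeneic 2 that list had a camera adjusted p of 0.18 (range 5.19e-08 to 0.521), and Rdh7 did not pass without syngeneic 1 (0.175; range 3.28e-11 to 0.175). Oxidative phosphorylation genes had a median of 0.48, with 0 of 75 members called by edgeR (0 adjusted over the list alone), and -0.14 without allogeneic 2.

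In library order, leaving 1 library out gave 123, 150, 3317 and 1788 changed genes in enterocyte-like cells, and the class had a median mitochondrial share of 10.35%, 10.25%, 14.48% and 7.99%.

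In Paneth-like cells antigen-presentation genes rose, and Lyz1 and defensin genes fell, in a class that 2 clusters supplied unequally. Cluster 10, led by defensin genes, held 220, 179, 59 and 36 of its cells in library order, and cluster 11, led by Reg4, Mmp7 and Spink4, held 110, 124, 145 and 109. The values below were not taken within either cluster. Cd74, the chaperone of MHC class II, averaged 1257 ± 11.5 CPM in the syngeneic and 5202 ± 1597 in the allogeneic libraries (SD, n = 2 pools; log2 fold change 2.05, SE 0.30, adjusted p = 0.0019), and H2-Aa, a class II chain, rose from 256 ± 15.6 to 1396 ± 275 CPM (2.45, adjusted p = 0.000458). B2m rose from 313 ± 25.7 to 1947 ± 660.0 CPM (2.64, adjusted p = 0.000458). Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868), which codes for lysozyme, fell from 44180 ± 9575 to 16800 ± 1353 CPM (-1.39, SE 0.27, adjusted p = 0.0129). Among the alpha-defensin genes, Defa29 fell from 14140 ± 2604 to 2703 ± 414 CPM (-2.39, adjusted p = 0.000447), Defa21 by 1.54 and Defa22 by 1.36 on the log2 scale. These defensin genes are near-identical, so single members are uncertain, and with a mitochondrial limit of 10% Defa21 (0.06) and Defa22 (0.25) had the opposite sign.

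Of 8839 genes tested in Paneth-like cells, 115 rose and 35 fell. The interferon-gamma list had 21 of 23 members up (23 adjusted over the list alone; median 3.04), MHC class I 12 of 18 (15; median 1.56), MHC class II 8 of 9 (9; median 1.88) and the interferon-stimulated list 5 of 15 (13; median 1.63), the counts in parentheses being adjusted over the list alone. Camera called each of them higher (adjusted p = 0.125 with an estimated correlation). Early-response and heat-shock genes moved with them, with 6 of 21 up (12 adjusted over the list alone; median 0.89, camera 2.94e-15, and 0.325 with an estimated correlation). Gbp4 had 0 counts in the syngeneic libraries and was at least 45.6-fold higher, from a floor of 3 counts over the group. Of 14 Paneth markers 6 fell (8 adjusted over the list alone; median -0.94, camera 4.99e-08, and 0.423 with an estimated correlation). Unfolded protein response genes, which secretory cells rely on, had a median of -0.43 (1 of 19 down, and 1 adjusted over the list alone; camera 0.000564, and 0.435 with an estimated correlation). The goblet lectin gene Zg16 fell from 92.1 ± 6.79 to 9.17 ± 2.66 CPM (-3.41, adjusted p = 6.5e-05), in a list of goblet markers with 1 of 12 down (2 adjusted over the list alone; median -0.36, camera 2.96e-05, and 0.36 with an estimated correlation). Of 3 enteroendocrine markers 1 fell (3 adjusted over the list alone; median -2.05, camera 3.05e-05, and 0.309 with an estimated correlation), a call lost without allogeneic 1 (0.149; range 6.04e-06 to 0.309).

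Leaving out 1 library gave 79, 77, 592 and 975 changed genes in Paneth-like cells, in library order, and 8, 7, 14 and 14 of the 14 named changed genes still passed. Lyz1 did not pass without syngeneic 1 or 2 (0.0877 and 0.618; all alternatives 2.63e-08 to 0.618), and neither did Cd74 (0.084 and 0.0858; 1.9e-37 to 0.0858), Defa21 (0.05275 and 0.282; 2.25e-13 to 0.986) or Defa22 (0.138 and 0.577; 2.17e-08 to 0.864).

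In goblet-like, enteroendocrine-like and tuft-like cells, camera called the interferon-gamma, MHC class I and MHC class II lists higher. In goblet-like cells no single gene passed over 9671 tested genes (0 by edgeR, 602 at an unadjusted p under 0.05, 85 by DESeq2). Cxcl9 averaged 3.70 ± 0.0979 and 135 ± 41.4 CPM there (log2 fold change 5.16, adjusted p = 0.108), B2m 399.7 ± 13.7 and 2718 ± 1137 (2.76, adjusted p = 0.386), and the mucin gene Muc2 3910.0 ± 145 and 3668 ± 1602 (-0.09, adjusted p = 0.979). Adjusted over the list alone, 21 of 23 interferon-gamma genes (median 2.99), 15 of 18 MHC class I genes (1.94) and 9 of 9 MHC class II genes (1.90) rose, all of them with 0 called over all genes; their adjusted p values with an estimated correlation were 0.315, 0.315 and 0.219. Enterocyte markers had a median of 2.68 in goblet-like cells (camera 5.96e-06, and 0.664 with an estimated correlation), but -0.15 without allogeneic 2, which supplied 78 of the 103 cells of the goblet cluster 20. In library order, leaving 1 library out gave 19, 26, 3468 and 1268 changed genes.

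In enteroendocrine-like cells 24 genes rose and 5 fell of 3142. Chga, a protein of hormone granules, rose from 690.1 ± 201 to 2206 ± 483 CPM (log2 fold change 1.67, adjusted p = 0.00719), and Cck, the gene of the hormone cholecystokinin, fell from 1841 ± 222 to 599 ± 170.3 CPM (-1.61, adjusted p = 0.00963). Gbp2 rose by 3.83 and B2m by 2.03. The interferon-gamma list had 6 of 10 members up (8 adjusted over the list alone; median 1.90, adjusted p = 0.126 with an estimated correlation). MHC class I genes had 6 of 15 up (12 adjusted over the list alone; median 1.52, and 0.126 with an estimated correlation) and class II genes 1 of 7 (7; median 1.25, and 0.226). Leaving 1 library out gave 20, 10, 151 and 64 genes in library order, and 3, 3, 9 and 8 of the 9 named changed genes still passed. Without syngeneic 1 or syngeneic 2 the adjusted p was 0.126 and 1.0 for Chga (all alternatives 1.96e-13 to 1.0), 0.26 and 1.0 for Cck (1.32e-10 to 1.0) and 0.108 and 0.334 for B2m (6.88e-17 to 0.334), and without syngeneic 2 it was 0.0521 for Gbp2 (4.68e-07 to 0.126).

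In tuft-like cells 14 genes rose and 1, Olfm4 (2080.0 ± 336 to 618 ± 232 CPM, -1.75, adjusted p = 0.0419), fell of 3627. In T or NK-like cells Olfm4 stood at 1002, 249, 113.4 and 5.179 CPM in library order. The 17 UMIs of syngeneic 1 lay in 2 of 10 cells, and the 15 of syngeneic 2 in 1 of 32. These values therefore cannot tell whether free Olfm4 RNA was also lower in the allogeneic libraries. Fabp1, a fatty acid carrier abundant in enterocytes, rose from 17.3 ± 9.75 to 739 ± 540.4 CPM (5.25, adjusted p = 0.00617), beside a median of 1.78 for enterocyte markers (1 of 11 up, 5 adjusted over the list alone; camera 2.99e-14, and 0.307 with an estimated correlation). H2-Q7 rose by 3.49, and Dclk1, a tuft cell marker, had a log2 fold change of 0.10 (adjusted p = 0.996). The interferon-gamma list had 4 of 12 members up (11 adjusted over the list alone; median 2.41, adjusted p = 0.222 with an estimated correlation). MHC class I genes had 6 of 15 up (10 adjusted over the list alone; median 1.49, and 0.222 with an estimated correlation) and class II genes 0 of 7 by edgeR (5 adjusted over the list alone; median 0.93, and 0.388). Leaving 1 library out gave 32, 17, 384 and 101 genes in library order, and 5, 4, 6 and 5 of the 6 named changed genes still passed. Olfm4 did not pass without syngeneic 1 (0.4995) or syngeneic 2 (0.154; all alternatives 1.71e-32 to 0.4995).

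The allogeneic effect differed between stem-like cells and other classes for named genes, tested as an interaction with library as a block. Against enterocyte-like cells, the effect was larger in stem-like cells for Ubd by 3.92 (SE 0.63, adjusted p = 5.42e-07), for Cxcl10 by 4.87 and for Gbp2 by 1.55 on the log2 scale, and the difference was -1.39 for Reg3g and -1.75 for Ccl25. Such a difference passed for 205 of 10080 genes (82 higher and 123 lower in stem-like cells), and for 27, 23, 500 and 625 without each library, in library order. By list it was 0.78 for interferon-gamma-inducible genes (camera 0.0317), 1.14 for G2 and M phase genes (4.19e-05), 0.81 for early-response genes (0.00132) and -0.40 for oxidative phosphorylation (3.46e-06), each with an adjusted p of 0.841 with an estimated correlation. The interferon-stimulated genes shared with type I interferon (0.446, camera 0.537) were not called. Neither were MHC class I (0.256, 0.165) and MHC class II genes (0.179, 0.232).

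Against cycling progenitor-like cells, the effect differed for Ube2c by 1.72 (SE 0.15, adjusted p = 8.59e-19), Cenpa by 1.52 and Mki67 by 1.13, and the difference was -2.96 for Cxcl9 (adjusted p = 0.00565). It passed for 207 of 10275 genes (105 higher and 102 lower in stem-like cells), and for 37, 62, 224 and 347 without each library, in library order. Goblet markers differed by -1.92 (camera 1.09e-11), regeneration-linked genes by -0.81 (1.1e-05) and G2 and M phase genes by 1.12 (1.31e-39), each with an adjusted p of 0.334 with an estimated correlation. S-phase genes (-0.407, camera 9.63e-07, and 0.594 with an estimated correlation) and MHC class II genes (-0.185, 0.0336, and 0.637) were called lower. The interferon-gamma list (-0.34, camera 0.191), the type I interferon list (0.0265, 0.659) and MHC class I genes (-0.0247, 0.823) were not called. Both allogeneic stem-like samples differ from the syngeneic ones in the clusters that supplied them, and allogeneic 2 gave 55 stem-like cells.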

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

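The tests for stretches of intestine and for free goblet RNA were chosen only after the results they measure were seen, as were the limits on what the doublet, intestine and summed-class tests can show and the depth tests by cell and by counting error.

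The interaction test between stem-like and enterocyte-like cells passed for 205 genes, so the allogeneic effect differed between these classes. The difference, stem-like minus enterocyte-like on the log2 scale, was 4.87 for Cxcl10, 3.92 for Ubd and 1.55 for Gbp2, all interferon-response genes. It was -1.39 for Reg3g, -1.21 for Reg3b and -1.75 for Ccl25, 3 genes also found in lymphocytes, the gauge of free RNA, and -1.67 for Ly6e. For the early-response genes Egr1 and Klf6 it was 1.71 and 1.45. Between stem-like and cycling progenitor-like cells the same test passed for 207 genes. There the difference was -2.96 for Cxcl9, 1.04 for Klf6, 1.13 for Mki67, 1.72 for Ube2c and 1.52 for Cenpa. Cluster 21, which stayed unnamed and entered no class comparison, held 102 cells, all of allogeneic 2, against 0 of 5327 syngeneic cells.

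The 2 allogeneic libraries differed from each other more than the 2 syngeneic ones, with a ratio of 3.114 between the SDs of their log2 differences over epithelial genes. With equal numbers of cells per class from each library the ratio was 2.452 (2.34 to 2.557 over 20 draws), which argues against the mix of classes as the whole source. With the library totals thinned to the smallest it was 3.125 (3.104 to 3.132) and with each cell thinned to 2000 UMIs 2.883 (2.855 to 2.91), while counting error alone would give 0.945, which argues against depth. In enterocyte-like cells, genes of the distal small intestine differed between the allogeneic libraries by a median of -0.12 (quartiles -0.544 to 0.614) and proximal genes by -0.493 (-1.133 to -0.147), so cells from different stretches of intestine remain possible and untested by a clear value. A difference between the pools of mice in how far disease had gone was not tested and stays open too.

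Genes of the G2 and M phases were higher in stem-like cells of the allogeneic group, with a list median of 1.22. In the sum of stem-like and cycling progenitor-like cells the median was 0.1138, where a rise in stem-like cells alone would have given 0.164 and no rise 0.0776, both under the bound set beforehand, so cells that lie on another side of the border between both classes stay open. Doublets with cycling cells stay open: removing the cells with the highest doublet scores left a median of 1.217, but took out 5 of 1077 stem-like cells (0.46%), too few for the test to tell. The value met the bound set beforehand against doublets, and that bound was wrong because it did not ask how many cells the setting would remove. Whether stem cells of allogeneic recipients divide more often was not tested.

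Goblet marker genes were higher in cycling progenitor-like cells of the allogeneic group, with a list median of 3.52, but with a mitochondrial limit of 10% Muc2 had a log2 fold change of 0.0097, Tff3 of 1.01 and Atoh1 of 0.68, none of which passed. Free RNA from goblet cells would raise them in other classes of the same libraries, and in enterocyte-like cells their median was 0.008472 (quartiles -0.678 to 0.265 over 9 genes), which argues against it as the whole source, while a part stays open because the median was 0.75 in stem-like cells. In the sum of cycling progenitor-like and goblet-like cells the median was -1.032. A rise in cycling progenitor-like cells alone would have given -0.975 and no rise -1.32, both under the bound set beforehand. Goblet precursors assigned to another class in the 2 groups therefore stay open. Cell numbers by cluster went with such a reassignment but were not used as a test. In library order, cluster 8, named goblet, held 270, 226, 128 and 17 cells, and cluster 5, named cycling progenitor, 6, 8, 126 and 658. Without the called genes, an unnamed cluster led by goblet genes scored highest as cycling progenitor and held 282, 242, 209 and 484 cells. A true shift of progenitors toward the secretory fate was not tested apart from this and stays open.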

How the results depend on the processing

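Removing the highest doublet scores, leaving out unnamed clusters and clustering without called genes were chosen only after results were seen. Directions held widely: of values for named genes under alternatives, 1820 kept direction and side of the threshold, 266 missed it, 38 newly passed and 11 reversed; for called lists, 502 kept it, 299 missed it and 15 reversed in the direction of the set test. Calls of lists did not hold with an estimated correlation. With 2 pools per group, the least depth was in enteroendocrine-like (129925 to 407224 UMIs) and tuft-like cells (199544 to 364089) and in stem-like cells of allogeneic 2 (213598), and the largest spread in goblet-like cells (biological coefficient of variation 0.299). No paired analysis was possible because the labels give the libraries no shared numbers. For enteroendocrine-like and tuft-like cells the setting of at least 1000 genes and 2500 UMIs left too few cells and gave no value. Where one library is left out, the lone sample of its group is assumed to vary like the other group. Except where a setting itself tests fewer genes or cells, the cause was not tested.

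DESeq2's Wald test called 331 epithelial, 54 stem-like, 320 enterocyte-like and 85 goblet-like genes. With DESeq2's size factors 420 genes differed between stem-like and enterocyte-like cells. At least 1000 genes and 2500 UMIs gave 75 stem-like genes and a T or NK-like log2 ratio of 3.57 (adjusted p = 0.0512). Clustering without called genes gave 3.18 (0.262). Over all alternatives this adjusted p ran from 0.000435 to 0.846. Camera with an estimated correlation called 0 lists in each of the 8 fits (8, 5, 4, 1, 5, 3, 3 and 5 at an unadjusted p under 0.05 in epithelial, stem-like, cycling progenitor-like, enterocyte-like, Paneth-like, goblet-like, enteroendocrine-like and tuft-like cells), and fry called 0, 9, 0, 1, 2, 2, 3 and 0 in that order (12, 12, 9, 10, 7, 5, 4 and 5 unadjusted). With classes assigned per cell (1210 cells lay within 0.1 of a border), the counts were 106 stem-like, 375 cycling progenitor-like, 65 Paneth-like, 23 goblet-like, 2 enteroendocrine-like and 25 tuft-like genes, Mki67 in stem-like cells -0.090, Dclk1 in tuft-like cells -0.12 and T or NK-like 3.08 (0.159). An equal mix of classes gave 203 epithelial genes. Without the highest doublet scores there were 371 stem-like, 95 Paneth-like and 23 tuft-like genes, and T or NK-like 3.21 (0.0837). A mean of at least 20 CPM, which tests fewer genes except in enteroendocrine-like and tuft-like cells, gave 0 epithelial (395 unadjusted, edgeR), 176 cycling progenitor-like, 72 enterocyte-like and 86 Paneth-like genes. In enteroendocrine-like cells it tested 6052 genes, against 3142 in the main fit, and gave 58. No low-count filter gave 528 epithelial, 338 stem-like, 1081 cycling progenitor-like, 808 enterocyte-like, 287 Paneth-like, 78 goblet-like, 53 enteroendocrine-like and 80 tuft-like genes.

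A mitochondrial limit of 10% gave 0 epithelial (1009 unadjusted, edgeR), 59 stem-like, 331 cycling progenitor-like, 524 enterocyte-like, 62 Paneth-like and 14 goblet-like genes, Lyz1 in cycling progenitor-like cells -0.068, Defa21 0.063 and Defa22 0.25 in Paneth-like cells, Dclk1 in tuft-like cells -0.25 and T or NK-like 3.46 (0.0625). A limit of 40% gave 33 epithelial, 79 stem-like and 51 enteroendocrine-like genes, Smoc2 0.11 and Mki67 -0.43 in stem-like cells and T or NK-like 2.96 (0.171). With the response lists kept in clustering there were 1 goblet-like and 24 tuft-like genes and a stem-like share ratio of 0.52. Thinned to the smallest library, there were 39 stem-like, 88 Paneth-like and 19 enteroendocrine-like genes.

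Leaving out each library gave ranges of 96 to 5719 epithelial, 40 to 1180 stem-like, 284 to 3800 cycling progenitor-like, 123 to 3317 enterocyte-like, 77 to 975 Paneth-like, 19 to 3468 goblet-like, 10 to 151 enteroendocrine-like and 17 to 384 tuft-like genes, 23 to 625 and 37 to 347 genes that differed between stem-like and enterocyte-like or cycling progenitor-like cells, and called lists of 19 to 23, 13 to 16, 10 to 14, 9 to 12, 12 to 15, 15 to 24, 8 to 9 and 13 to 20 in the same order of fits. Share ratios ranged from -3.33 to 0.67 (stem-like), -0.27 to 0.80 (enterocyte-like), -1.93 to -0.091 (Paneth-like), -1.88 to -0.43 (goblet-like), -1.06 to 0.0042 (tuft-like) and 2.32 to 4.44 (T or NK-like). Lgr5 in epithelial cells ranged from -1.33 to 0.12, Muc2 in goblet-like cells from -0.62 to 0.28 and Dclk1 in tuft-like cells from -0.46 to 0.48. Where the direction of the set test reversed, list medians ranged, for oxidative phosphorylation, from -0.19 to 0.75 (epithelial), -0.14 to 0.95 (enterocyte-like), -0.19 to 0.65 (goblet-like) and -0.14 to 0.60 (tuft-like). Stem markers ranged from -0.95 to 0.11 (epithelial) and -1.69 to 0.20 (goblet-like). In goblet-like cells glycolysis ranged from -0.10 to 0.92, Wnt targets from -1.44 to 0.29, S phase from -0.85 to 0.094, distal genes from -0.15 to 2.11, absorption from -0.044 to 2.86, enterocyte markers from -0.15 to 3.54 and general epithelial markers from 0.050 to 1.26 with no change of sign. Paneth markers in enteroendocrine-like cells ranged from -5.69 to -0.064, again with no change of sign, and glycolysis in tuft-like cells from -0.093 to 0.78.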

Other observations

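The genes in this part were chosen after their values were seen, and no test was run on the lymphocytes or on cluster 21.

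T or NK-like cells carried genes of cytotoxic lymphocytes in both groups. In library order the granzyme genes Gzma and Gzmb stood at 5656, 21130, 17110 and 8848 CPM and at 1237, 4897, 3893 and 5021 CPM. Ifng, the gene of interferon gamma, stood at 117.8 CPM in syngeneic 1 (95% Poisson interval 14.3 to 426), 66.4 in syngeneic 2 (18.1 to 170.0), 190.9 in allogeneic 1 (155.5 to 231.9) and 512.7 in allogeneic 2 (443.8 to 589.3). Cd8a stood at 353.5, 929.6, 727.6 and 569.6 CPM and Cd4 at 0, 0, 18.9 and 28.5. Itgae, the integrin chain of lymphocytes that reside in the epithelium, stood at 295, 382, 166 and 5.18 CPM. Syngeneic 1 held 10 such cells and syngeneic 2 held 32, so no test was run. Epithelial RNA was present in these cells, with Reg3b at 177, 15260.0, 1455 and 5961 CPM. Whether it was free RNA or came from doublets was not tested.

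The 102 cells of cluster 21 were marked by Car1, a carbonic anhydrase gene, at 57100.0 CPM, against 0, 0.149, 0 and 83.5 CPM in the other epithelial cells of each library in order. S100g stood at 4490.0 and Selenbp1 at 1810.0 CPM in this cluster. With 0 of 5327 syngeneic cells in it, a syngeneic share of up to 0.0563% is allowed.

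In cycling progenitor-like cells Usp18 had 0 syngeneic counts and was at least 22.2-fold higher in the allogeneic group, from a floor of 3 counts over the group. In goblet-like cells H2-DMb2 was at least 45.4-fold higher on the same floor, and in tuft-like cells Ido1 at least 50.3-fold. Of these 3, Usp18 passed the test over all genes (adjusted p = 0.000337), while H2-DMb2 (0.182) and Ido1 (0.318) did not.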
